A study of Homo sapiens with 8 samples.

How the data were processed

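ChIP-seq of H3K27me3, EZH2 and H3K4me3 was analysed in the diffuse large B cell lymphoma lines HT and SUDHL6, with 1 library for each line and antibody and no treatment. The 2 input samples, 1 per line, were not used here. The authors deposited 1 list of islands per library, so islands were called per library and not on pooled samples. SICER and hg19 are named in the submitters' processing notes. The deposited file names give a window of 150 bp, a gap of 450 bp and an FDR of 1E-7. In the files, island starts and ends fell on the 150 bp grid and neighbouring islands were at least 600 bp apart. The aligner, the read filters, the control used in calling and the sequencing depth were not given in the sources used here. The H3K27me3 lists carry another normalization tag in their names than the EZH2 and H3K4me3 lists, and its meaning was not given in the sources used here, so levels were not compared between antibodies.

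Each deposited list holds the chromosome, start, end and a score per island. This score is the authors' own value and was used only to rank, select or describe islands within its list. What it counts was not given in the sources used here. A sum or number of islands moves with how much was called in a library, so number and covered length are given together. Positions are hg19, counted from 1.

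Islands were compared by overlap of at least 1 bp. Shares have exact (Clopper-Pearson) 95% intervals that cover counting error only. Beside the main overlaps, the islands of 1 list were moved by 1000 random circular shifts along each chromosome. As an addition after the data were seen, they were also moved by 1000 shifts of 0.5 to 2 Mb, which keep regional clustering. No shifts were run for EZH2 islands classed by line or by both marks, or under the alternative settings. The shifts describe these lists and give no p-value for the lines. The overlap steps were checked on simulated islands, and 100% of the islands of each list size were classed rightly. Covered length per chromosome is given as the log2 ratio HT over SUDHL6 minus that over chromosomes 1 to 22. Regional values were taken in windows of 10 Mb, with 3 kb added to both lines before ratios and, for relations between antibodies, at least 50 kb of H3K4me3 in both lines together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

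Regions were named by a rule fixed before the data were examined: the 5 widest islands of each list, the 5 widest without an island of the other line, and the 5 widest H3K27me3 islands present in both lines. Islands present in both lines were ranked by the narrower island of each overlapping pair. The text gives the leading regions. The windows and the segments holding the 20 widest H3K27me3 islands were chosen after their values were seen. Alternatives fixed beforehand were an overlap of at least 50% of the island, the 50% of each list with the highest scores, chromosomes 1 to 22, islands of at least 1 kb, islands within 5 kb joined, and both lines held to the same number of islands or the same covered length. Planned counts of promoter states and of gene lists needed gene positions on hg19 and were not run, so islands are not assigned to genes.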

Results

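The genomic distribution of trimethylated lysine 27 of histone H3 (H3K27me3), of the methyltransferase EZH2 and of trimethylated lysine 4 of histone H3 (H3K4me3) was measured by ChIP-seq in HT and SUDHL6, established cell lines of diffuse large B cell lymphoma grown without treatment. EZH2 is the catalytic subunit of Polycomb repressive complex 2, which writes H3K27me3, a mark of repressed chromatin, and H3K4me3 marks active promoters. Each of the 6 combinations of line and antibody had 1 library, and each library had 1 list of enriched islands on hg19. No line had a replicate, so no test between the lines was made. Shares are given with exact (Clopper-Pearson) 95% intervals, which cover counting error only. Read depth was not given in the sources used here.

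H3K27me3 covered nearly the same total length in both lines but was spread over fewer and wider islands in SUDHL6. HT had 16919 H3K27me3 islands over 54.4 Mb and SUDHL6 had 13159 over 51.3 Mb. EZH2 covered 10.99 Mb in 2523 islands in HT and 8.77 Mb in 1506 islands in SUDHL6. H3K4me3 went the other way, with 10914 islands over 25.5 Mb in HT and 13736 over 33.0 Mb in SUDHL6. The log2 ratio of covered length, HT over SUDHL6, was 0.08 for H3K27me3, 0.33 for EZH2 and -0.37 for H3K4me3. The near equality of H3K27me3 came from opposite differences by position, with 8.99 Mb in HT and 21.3 Mb in SUDHL6 in the outer 10 Mb of the autosomes and a log2 ratio of 0.59 for islands over 10 Mb from the ends.

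The median H3K27me3 island was 2550 bp wide in HT and 3000 bp in SUDHL6. Islands of 10 kb or wider made up 2.19% (1.97 to 2.42%) of the HT list and 4.61% (4.26 to 4.99%) of the SUDHL6 list, and held 5.61 Mb and 8.80 Mb. At 50 kb or wider the order turned, with 3 islands in HT and 0 in SUDHL6. With islands within 5 kb joined, those of 10 kb or wider were 9.93% of the HT list and 16.9% of the SUDHL6 list. EZH2 islands of 10 kb or wider were 3.45% (2.77 to 4.24%) of the HT list and 11.8% (10.2 to 13.6%) of the SUDHL6 list.

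The widest H3K27me3 islands of HT were gathered in a few chromosome segments, and those of SUDHL6 less so. In HT the leading islands lay on chromosome 10 from 73450801 to 73519500 (68.7 kb) and on chromosome 11 from 113798851 to 113860800 (61.95 kb) and from 116556151 to 116606850 (50.7 kb). SUDHL6 H3K27me3 covered 44.1%, 22.8% and 22.8% of these islands. Of the 20 widest HT islands, 11 lay between 110 and 120 Mb of chromosome 11, and all 20 lay in 3 windows of 10 Mb. In SUDHL6 the leading islands lay on chromosome 6, from 43207651 to 43257000 (49.35 kb), 37497751 to 37542450 (44.7 kb) and 32006401 to 32045700 (39.3 kb), with 27.7%, 57.0% and 4.58% of their length covered by HT H3K27me3. Of the 20 widest SUDHL6 islands, 8 lay between 30 and 40 Mb of chromosome 6, and the 20 lay in 8 windows. All 20 HT islands and 16 of the 20 SUDHL6 islands lay in windows with relatively more H3K4me3 in the same line, a class that held 56.1% and 43.9% of all windows compared. Islands in the same window are not independent.

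Most H3K27me3 and EZH2 islands of each line overlapped no island of the other, whereas most H3K4me3 islands had such an overlap. With 1 library each and unknown depth, a missing island is not absence of the mark. How far replicate libraries of the same line would overlap is not known for any antibody, so calling and line cannot be told apart here. An island of the other line was overlapped by 21.2% (20.6 to 21.8%) of HT and 27.8% (27.1 to 28.6%) of SUDHL6 H3K27me3 islands. The shares were 11.5% (10.2 to 12.8%) and 19.4% (17.4 to 21.5%) for EZH2, and 74.4% (73.6 to 75.2%) and 59.0% (58.1 to 59.8%) for H3K4me3. Of the bases covered in either line, 10.2% were covered in both for H3K27me3, 6.07% for EZH2 and 34.6% for H3K4me3. Every share lay above all 1000 random circular shifts of the islands, whose means ran from 0.672% for HT EZH2 to 4.75% for SUDHL6 H3K27me3. The number of overlapping islands was nearly the same counted from either line (3588 and 3661 for H3K27me3, 289 and 292 for EZH2, 8122 and 8099 for H3K4me3), so the order of the lines in these shares only mirrors which list is longer.

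**Figure D1:**
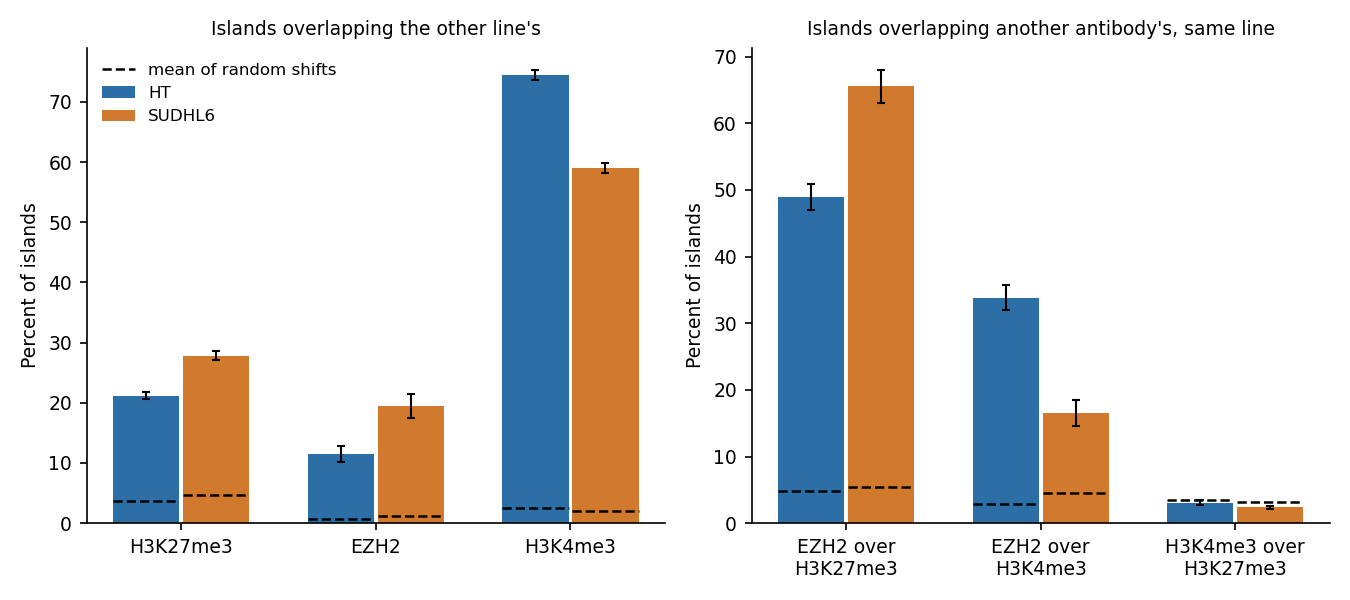
Percent of islands overlapping an island of the other line (left) or of another antibody in the same line (right), by at least 1 bp. Bars are single libraries, black bars are exact 95% intervals for counting error and dashed lines are means of 1000 random shifts. H3K4me3 islands were shared most often (74.4% in HT), and EZH2 lay over H3K27me3 in 48.9% of islands in HT and 65.5% in SUDHL6.

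Overlapping H3K27me3 islands of both lines were ranked by the width of the narrower island. The first pair spanned 234926251 to 234955950 of chromosome 1 in HT (29.7 kb) and 234935701 to 234952050 in SUDHL6 (16.35 kb). The next by this rank lay on chromosome 6, from 33818701 to 33834450 in HT (15.75 kb), inside a SUDHL6 island of 36.6 kb from 33815101 to 33851700. Wider islands of either line overlapped narrower islands of the other. The widest HT islands without SUDHL6 H3K27me3 lay on chromosome 11 from 112391251 to 112428150 (36.9 kb) and from 112684351 to 112720650 (36.3 kb). The widest SUDHL6 island without HT H3K27me3 lay near the start of chromosome 11, from 1989451 to 2025450 (36.0 kb), and SUDHL6 EZH2 covered 97.9% of it. The share of H3K27me3 islands present in the other line rose with width, from 8.05% (6.51 to 9.81%) below 1 kb to 64.2% (49.8 to 76.9%) at 20 kb or wider in HT and from 14.3% (11.6 to 17.3%) to 66.7% (54.0 to 77.8%) in SUDHL6. Islands moved by 0.5 to 2 Mb rose with width as well, from a mean of 3.53% to 22.03% in HT and from 4.80% to 23.5% in SUDHL6.

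EZH2 lay over H3K27me3 more often in SUDHL6 and over H3K4me3 more often in HT. H3K27me3 of the same line was overlapped by 48.9% (47.0 to 50.9%) of HT EZH2 islands and 65.5% (63.1 to 67.9%) of SUDHL6 EZH2 islands, against means of 4.84% and 5.50% for shifts along the whole chromosome. Shifts of 0.5 to 2 Mb, which keep regional clustering, had means of 7.06% and 14.1%. The share was 10.1 and 11.9 times the former means and 6.93 and 4.66 times the latter, so the order of the lines over random placement depended on the kind of shift. For islands over 10 Mb from chromosome ends, a setting chosen after the results were seen, the gap was smaller. The share over H3K27me3 was then 48.3% in HT and 56.5% in SUDHL6. H3K4me3 was overlapped by 33.8% (32.0 to 35.7%) of HT and 16.5% (14.6 to 18.4%) of SUDHL6 EZH2 islands, against means of 2.91% and 4.55% for whole-chromosome shifts and 3.98% and 7.02% for the near shifts. These shares fell to 18.9% and 7.57% with an overlap of 50% of the island, and to 21.6% and 8.10% within the 50% of each list with the highest scores. The latter setting also cut the H3K4me3 lists, so fewer islands could be met. Against the whole H3K4me3 list, the 1506 HT EZH2 islands with the highest scores had a share of 34.9%. EZH2 islands with H3K4me3 and no H3K27me3 were 26.6% (24.9 to 28.4%) of the HT list and 10.8% (9.30 to 12.5%) of the SUDHL6 list. Neither mark was present at 24.4% (22.7 to 26.1%) and 23.6% (21.5 to 25.9%).

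**Figure D2:**
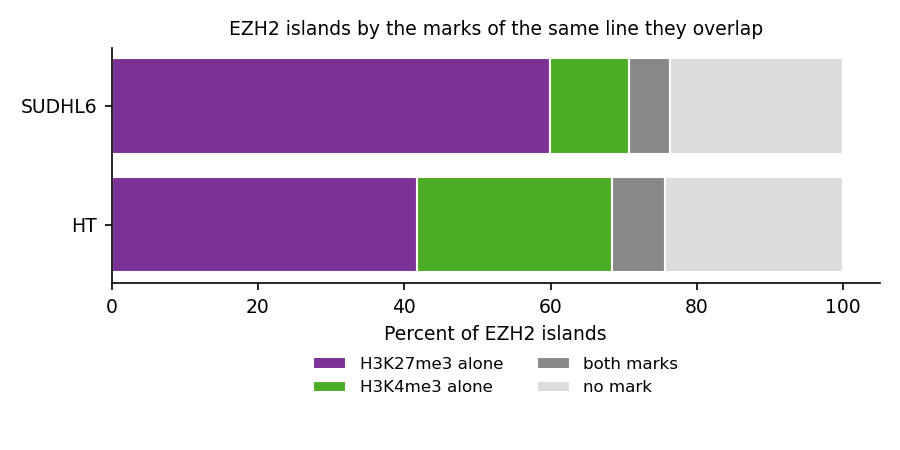
EZH2 islands of each line (HT 2523, SUDHL6 1506), in percent, by overlap of at least 1 bp with H3K27me3 or H3K4me3 islands of the same line. The segment over H3K4me3 alone is 26.6% in HT and 10.8% in SUDHL6.

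Wider H3K27me3 islands held EZH2 more often. In HT the share with EZH2 was 1.54% (0.898 to 2.45%) below 1 kb and 24.9% (20.3 to 30.1%) from 10 to 20 kb, and it was 17.0% (8.07 to 29.8%) for the 53 islands of 20 kb or wider. In SUDHL6 it was 3.69% (2.35 to 5.48%) below 1 kb, 31.2% (27.4 to 35.3%) from 10 to 20 kb and 39.4% (27.6 to 52.2%) for the 66 islands of 20 kb or wider. Islands placed by shifts of 0.5 to 2 Mb also met EZH2 more often when wider, up to a mean of 5.32% in HT and 8.87% in SUDHL6 at 20 kb or wider. The HT shares below 1 kb and at 20 kb or wider lay within the range of these shifts, whose highest values were 1.63% and 18.9%.

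**Figure D3:**
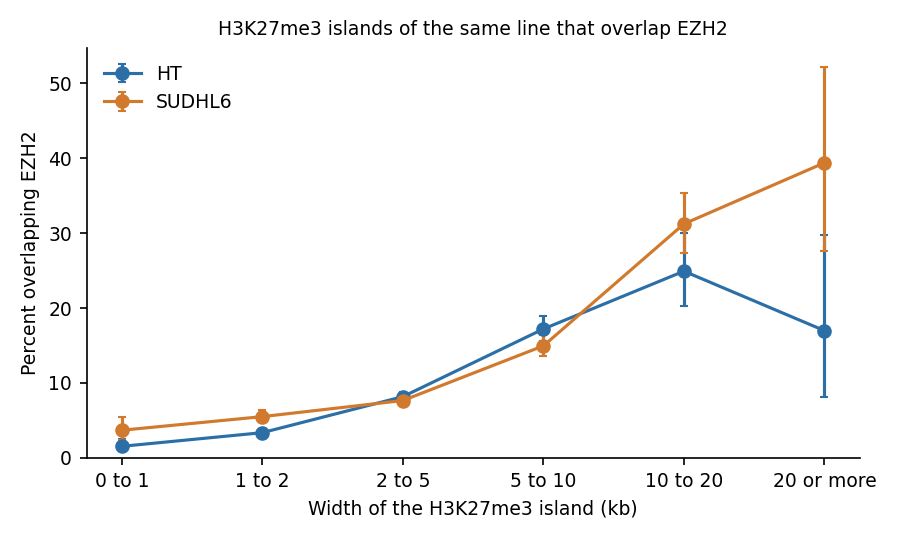
Percent of H3K27me3 islands overlapping EZH2 of the same line, by width of the H3K27me3 island in kb. Points are single libraries with exact 95% intervals for counting error, and the share from 10 to 20 kb was 24.9% in HT and 31.2% in SUDHL6.

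The widest EZH2 islands included a segment common to both lines and several found in 1 line. The widest in both lists lay on chromosome 19, from 50594101 to 50643600 in HT (49.5 kb) and from 50593951 to 50644200 in SUDHL6 (50.25 kb). SUDHL6 H3K27me3 covered 97.3% and SUDHL6 H3K4me3 78.2% of the SUDHL6 island, and no HT island of either mark lay there. The SUDHL6 H3K4me3 island in this segment was 39.3 kb wide, against a median of 1950 bp in its list. SUDHL6 H3K27me3 covered 98.5% and SUDHL6 EZH2 100% of it. The segment was not checked against input, so true enrichment there is not established. In HT, EZH2 islands of 36.9 kb and 31.8 kb lay on chromosome 2 from 54990301 to 55027200 and from 55225351 to 55257150, with no H3K27me3 in either line. In SUDHL6, an EZH2 island of 39.45 kb lay on chromosome 6 from 36698851 to 36738300, and SUDHL6 H3K27me3 covered 81.4% of it.

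Islands carrying both histone marks were few. H3K27me3 was overlapped by 3.10% (2.78 to 3.44%) of HT and 2.35% (2.10 to 2.62%) of SUDHL6 H3K4me3 islands. The shares lay below the means of random circular shifts (3.53% and 3.16%) and below all 1000 shifts of 0.5 to 2 Mb, whose means were 4.85% and 4.58%. With an overlap of 50% of the island the shares were 1.60% in HT and 0.786% in SUDHL6. Within the 50% of each list with the highest scores the order of the lines turned, with 1.26% in HT and 1.63% in SUDHL6. That setting also leaves fewer H3K27me3 islands to be met.

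EZH2 islands shared by the lines mostly lay in H3K27me3 present in both lines, and those of 1 line less often. Of the 289 HT EZH2 islands that overlapped a SUDHL6 EZH2 island, 64.7% (58.9 to 70.2%) had H3K27me3 in both lines. Of the 2234 EZH2 islands of HT alone, 32.5% (30.6 to 34.5%) had H3K27me3 in HT alone, 11.6% (10.29 to 12.99%) in both lines and 53.9% (51.8 to 56.0%) in neither. Of the 1214 EZH2 islands of SUDHL6 alone, the shares were 35.6% (32.9 to 38.4%) in SUDHL6 alone, 28.6% (26.1 to 31.2%) in both and 30.1% (27.6 to 32.8%) in neither. EZH2 of SUDHL6 alone thus lay over H3K27me3 of HT in 34.3% (31.6 to 37.0%) of islands, and EZH2 of HT alone over H3K27me3 of SUDHL6 in 13.5% (12.1 to 15.0%). With an overlap of 50% of the island throughout, these shares were 21.6% and 7.61%. No random shifts were run for these classes. The H3K27me3 list of HT was longer (16919 islands against 13159). EZH2 islands of the whole SUDHL6 list were wider (median 4500 bp against 3600 bp). How much of this difference random placement would give was not tested.

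The lines differed by chromosome more for H3K27me3 and EZH2 than for H3K4me3. Relative to the ratio over all autosomes, H3K27me3 covered more in HT on chromosomes 13 (log2 ratio 1.26), 5 (1.16) and 10 (1.13), and more in SUDHL6 on chromosomes 7 (-1.08), 19 (-1.03) and 6 (-0.97). By number of islands the ratio on chromosome 6 was 0.02, with 868 islands in HT and 667 in SUDHL6, so its direction turned. The log2 ratio was 0.5 or more in size on 15 of 22 autosomes for H3K27me3, 13 for EZH2 and 4 for H3K4me3. Chromosome 13 had the highest EZH2 ratio (2.503), from 70 islands in HT and 7 in SUDHL6. The H3K4me3 ratio was highest on chromosome 10 (0.55) and lowest on chromosomes 7 (-0.55), 6 (-0.55) and 9 (-0.50). Also by number of islands, 0 autosomes passed the limit for H3K4me3.

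Across the 22 autosomes the H3K27me3 ratio went with the EZH2 ratio (Pearson r = 0.73, Spearman rho = 0.70, and r = 0.64 without chromosomes 5 and 13), with the same direction on 17. The relation to the H3K4me3 ratio was weaker, with r = 0.43 and rho = 0.28 for H3K27me3 and r = 0.20 and rho = 0.09 for EZH2. The direction was the same on 14 and 11 autosomes. These were the 3 relations computed, and chromosomes of 1 pair of libraries are not replicates. On chromosomes 6, 7, 9 and 10, which passed the limit for H3K4me3, the covered-length ratios of all antibodies had the same direction. By number of islands this held on chromosomes 7, 9 and 10 but not on 6. There the ratio by number was 0.53 for EZH2, 0.02 for H3K27me3 and -0.25 for H3K4me3. Copy number would also give all antibodies the same direction and was not measured.

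**Figure D4:**
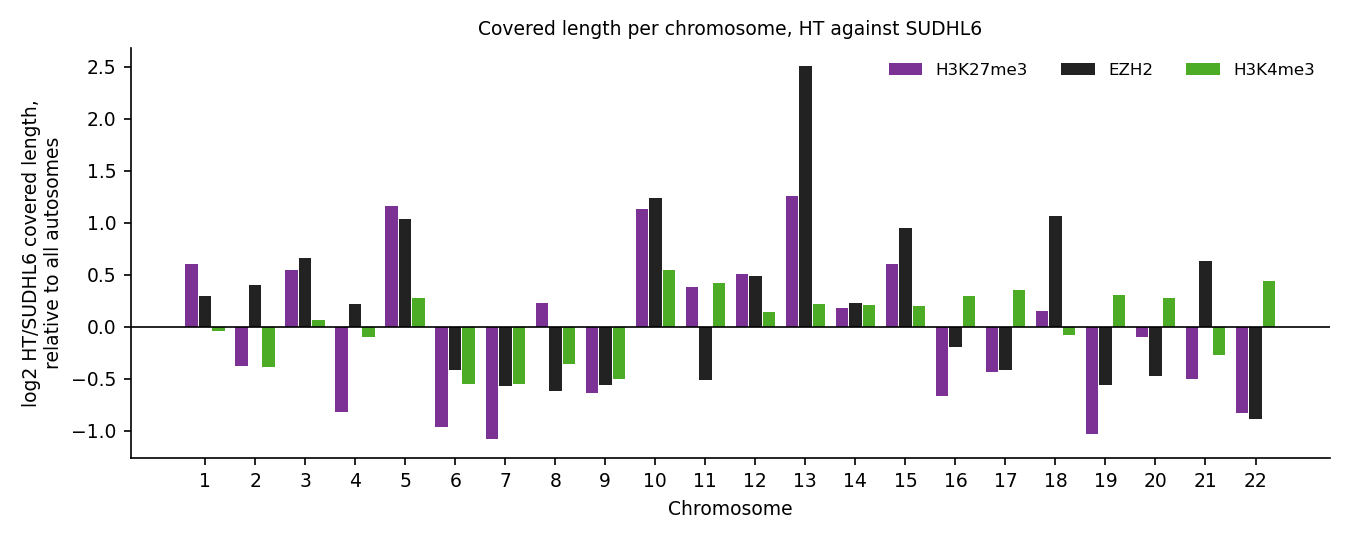
Log2 ratio of covered length, HT over SUDHL6, for each autosome relative to the ratio over all autosomes. Bars are pairs of single libraries, and the values run from -1.08 to 1.26 for H3K27me3 and reach 2.503 for EZH2 on chromosome 13.

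H3K27me3 and EZH2 lay nearer the ends of chromosomes in SUDHL6 than in HT, a measure chosen after the data were seen. The outer 10 Mb made up 15.3% of autosome length. They held 41.5% of the H3K27me3 length of SUDHL6 and 16.6% of that of HT, with SUDHL6 higher on 22 of 22 autosomes. For EZH2 the shares were 44.4% in SUDHL6 and 16.8% in HT, with SUDHL6 higher on 21 of 22. For H3K4me3 they were 15.5% and 17.5%, with SUDHL6 higher on 8 of 22. Between 0 and 10 Mb of chromosome 4, H3K27me3 covered 983 kb in SUDHL6 and 39.1 kb in HT, and between 0 and 10 Mb of chromosome 7 it covered 1078 kb and 83.8 kb. On some autosomes the higher share came with less H3K27me3 at the ends and a shorter total. In the outer 10 Mb, SUDHL6 and HT covered 0.215 and 0.305 Mb on chromosome 3. They covered 0.139 and 0.159 Mb on chromosome 15, and 0.105 and 0.118 Mb on chromosome 18. The shares take both ends of an autosome together, and some single ends went the other way. Between 0 and 10 Mb of chromosome 8, H3K27me3 covered 6.9 kb in SUDHL6 and 111 kb in HT. Inside the chromosomes, HT covered 432 kb and SUDHL6 8.55 kb between 20 and 30 Mb of chromosome 8.

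**Figure D5:**
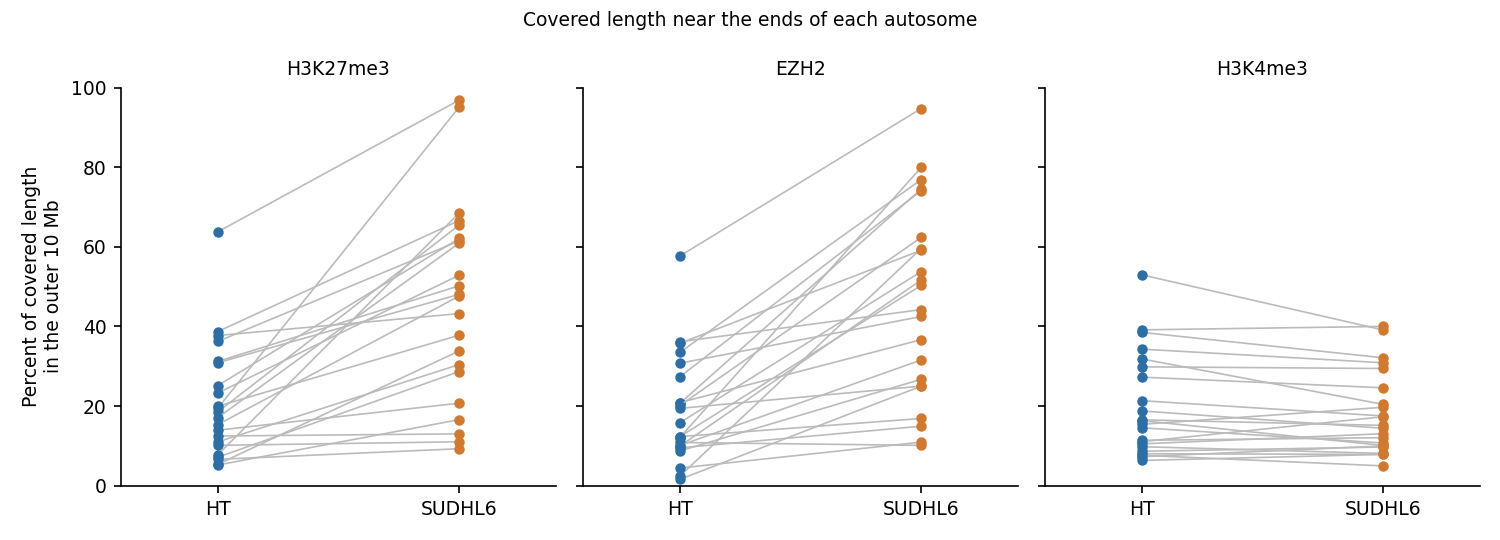
Percent of covered length in the outer 10 Mb of each autosome, for HT and SUDHL6. Each point is 1 autosome and grey lines join the same autosome, with SUDHL6 higher on 22 of 22 autosomes for H3K27me3, 21 for EZH2 and 8 for H3K4me3.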

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

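The tests of H3K4me3 at chromosome ends and of the order of neighbouring windows were chosen after the results were seen, as were the draw of whole chromosomes, the other settings of the windows and the demand that each of them meet the limit for copy number.

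The covered length of H3K4me3 was lower in HT (log2 HT over SUDHL6 of -0.37), whereas those of H3K27me3 and EZH2 were higher in HT. This difference between antibodies was not tested. The share of H3K4me3 length in the outer 10 Mb was likewise lower in SUDHL6 than in HT by a difference of -1.998 percentage points, against differences of 24.9 for H3K27me3 and 27.6 for EZH2, and the difference between these differences was not itself tested for lack of replicates.

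H3K27me3 of SUDHL6 lay nearer chromosome ends than that of HT. Copy number, or another property of the DNA, would move H3K4me3 the same way if it acted alike on all antibodies, and the H3K4me3 difference was -1.998 points. A property of the DNA that acts less on H3K4me3 is not excluded by this. Weak islands near the calling threshold would lose the difference among the 50% of islands with the highest scores, where it was 26.7 points. That ranking takes the score of the whole island and favours wide ones. The median width rose from 2550 to 3900 bp in HT and from 3000 to 4800 bp in SUDHL6. Wide islands of low score per kb can remain there, so the value speaks only to islands of low total score. The number of H3K4me3 islands per window, averaged over the lines, stood in for promoter density. Over the middle range of the end windows (18.5 to 53.1 islands), windows inside the chromosomes had a median log2 ratio 1.80 higher (95% bootstrap interval 0.70 to 2.81, or 0.78 to 2.87 drawing whole chromosomes, 150 and 31 windows). This argues against density as the whole cause. Inside the chromosomes the ratio fell with density (rho = -0.35 over 226 windows), so density may carry part of it. Base composition itself, the control used in calling and the normalization of the H3K27me3 lists were not tested, and no test of a biological difference between the lines was run, so both kinds of explanation stay open.

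H3K4me3 differed between the lines in runs of neighbouring windows. The log2 ratios of neighbouring windows had a correlation of 0.57 over 251 pairs, above the highest of 1000 random orders (0.17), which describes the pattern over all windows and tests no cause of it. Over the same pairs the correlation was 0.52 for H3K27me3 and 0.37 for EZH2, so runs were not particular to H3K4me3. Random orders were drawn for H3K4me3 only. Copy number of chromosome segments would move all antibodies together: away from chromosome ends, rho with the H3K4me3 ratio was 0.36 for H3K27me3 and 0.30 for EZH2 over 224 windows, and the limit set was 0.3. Over 9 settings of the windows, rho ran from 0.28 to 0.41 for H3K27me3 and from 0.20 to 0.35 for EZH2, and both met the limit in 3, so copy number and a regional difference in chromatin cannot be told apart without input libraries. All 20 of the widest HT H3K27me3 islands, and 16 of the 20 widest of SUDHL6, lay in windows with relatively more H3K4me3 in the same line (56.1% and 43.9% of all windows), but they fill only 3 and 8 windows, so this adds little.

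EZH2 islands of HT lay over H3K4me3 more often than those of SUDHL6. A longer HT list with islands of lower total score does not account for this. With 1506 islands in each list the HT share was 34.9% (32.5 to 37.4%) and the SUDHL6 share 16.5%. The HT islands were ranked by the score of the whole island, not per kb. Promoter background in the HT library could add EZH2 at the strongest H3K4me3 islands. The 25% of HT H3K4me3 islands with the highest score per kb held EZH2 1.33 times as often as the lowest 25% (8.89% and 6.67%), under the 2 times set for that explanation, and in SUDHL6, with less EZH2 over H3K4me3, the shares were 1.72% and 0.859%, a steeper rise. The EZH2 islands over H3K4me3 without H3K27me3 had the lower median score per kb (14 against 16.8, in the authors' units, whose meaning was not given in the sources used here), as background would give, so background and a difference between the lines cannot be told apart here.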

How the results depend on the processing

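The settings away from chromosome ends or from empty stretches, and all settings of the share near chromosome ends, were chosen after the results were seen. Values are given for HT and then SUDHL6. With an overlap of 50% of the island, shares present in the other line were 14.5% and 18.8% (H3K27me3), 9.43% and 14.3% (EZH2) and 66.3% and 51.5% (H3K4me3). EZH2 over H3K27me3 was then 41.9% and 51.7%, H3K4me3 over H3K27me3 1.60% and 0.786%, and EZH2 over H3K4me3 18.9% and 7.57%. EZH2 of 1 line alone lay over its own H3K27me3 in 37.7% and 51.6% and over that of the other line in 7.61% and 21.6%. In the 50% of islands with the highest scores these shares were 22.7% and 29.0% (H3K27me3), 83.7% and 66.7% (H3K4me3), 60.4% and 75.7%, 1.26% and 1.63%, 21.6% and 8.10%, 56.2% and 76.0%, and 11.04% and 40.6%. H3K27me3 islands were then 3900 and 4800 bp wide in the median, with 4.37% and 9.23% of 10 kb or wider. This setting kept all 370 and 607 islands of 10 kb or wider, so those shares rose only because the lists were cut. Islands of at least 1 kb gave 72.5% and 57.7% for shared H3K4me3. Joining gave 22.2% and 31.1% for shared H3K27me3, 75.7% and 60.7% for shared H3K4me3, and 9.93% and 16.9% of H3K27me3 islands at 10 kb or wider. The same number of islands gave 25.1% and 26.3%, 15.9% and 16.2%, and 71.3% and 70.9% for the shared islands of H3K27me3, EZH2 and H3K4me3, and the same covered length 24.1% and 26.7%, 15.3% and 17.1%, and 66.3% and 81.9%. Over 10 Mb from chromosome ends, shared H3K27me3 was 18.4% and 32.7%, shared H3K4me3 73.2% and 57.0%, and in SUDHL6 shared EZH2 was 23.7%, EZH2 over H3K27me3 56.5%, H3K4me3 over H3K27me3 2.09%, EZH2 over H3K4me3 20.3%, EZH2 of SUDHL6 alone over its own H3K27me3 53.4%, and H3K27me3 islands of 10 kb or wider 4.11%. In HT, EZH2 over H3K27me3 was 48.3% there, EZH2 over H3K4me3 34.2%, and EZH2 of HT alone over its own H3K27me3 43.9%. By number of islands, 0 autosomes passed the limit of 0.5 for H3K4me3. The order of the lines turned for shared H3K4me3 at the same covered length and for H3K4me3 over H3K27me3 among the highest scores. The order of the shared islands mirrors which list is longer and is not evidence in any setting. The order of the lines held under every setting run for EZH2 over either mark and EZH2 of 1 line alone (6), and H3K27me3 width (4). For islands of 10 kb or wider, the setting of highest scores could not change the order, since it kept every such island. The same number of islands makes the shares of both lines nearly equal by construction and says nothing on their order, and a 50% overlap can only lower a share over islands of another antibody. The highest scores were taken in both lists of an overlap, so part of a lower share there can come from fewer islands to be met. The other causes were not tested. The log2 ratio of covered length kept its sign in all 5 settings run for each antibody, and away from chromosome ends it was 0.59 for H3K27me3 and 0.90 for EZH2. Without islands within 5 Mb of the longest empty stretch of each autosome it was -0.33 for H3K4me3. By number of islands the H3K27me3 ratio of chromosome 6 was 0.02 in place of -0.97, and its EZH2 ratio 0.53 in place of -0.42. The outer 5 or 20 Mb gave differences in the H3K27me3 share of 21.6 and 20.4 points, and in the H3K4me3 share of -1.38 and -3.29 points. Promoter states and gene lists were not run under any setting, because gene positions on hg19 were not used here. With 1 library per line and antibody, no library could be left out. No paired analysis was possible because each line and antibody has 1 library. Depth was not given in the sources used here, so its effect on the number of islands is open.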

Other observations

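The test of H3K4me3 islands of 1 line against H3K27me3 of the other was chosen after the result was seen. H3K4me3 islands found in 1 line alone lay over H3K27me3 of the other line more often than over that of their own. Of the 5637 H3K4me3 islands of SUDHL6 alone, 6.69% (6.05 to 7.37%) overlapped H3K27me3 of HT and 2.34% (1.96 to 2.77%) H3K27me3 of SUDHL6 itself. Of the 2792 H3K4me3 islands of HT alone, 4.73% (3.97 to 5.58%) overlapped H3K27me3 of SUDHL6 and 3.33% (2.70 to 4.07%) that of HT. H3K4me3 islands shared by the lines did so in 3.02% or less. Island width or regional clustering could give such overlap, but over 1000 shifts of 0.5 to 2 Mb the highest share was 3.83% for the SUDHL6 islands and 4.66% for the HT islands. The interval of the SUDHL6 value lies above its highest shift. That of the HT value includes its highest shift, so clustering on the scale of the shifts stays open for the HT islands. Gathering of both lists in the same places below 0.5 Mb is lost in these shifts and stays open for both lines. Seen from H3K27me3, islands of HT alone lay over SUDHL6 H3K4me3 in 3.65% (3.33 to 3.98%), an interval that includes the highest shift of 3.55%. Those of SUDHL6 alone lay over HT H3K4me3 in 2.35%, below all 1000 shifts (lowest 3.25%). Sites with H3K27me3 in HT and H3K4me3 in SUDHL6 at a small minority of islands may exist as a hypothesis found and tested on the same lists, resting on the view from the SUDHL6 H3K4me3 islands, and the reverse exchange stays open.

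H3K27me3 and EZH2 islands were rare on chromosome X in both lines. It held 51 H3K27me3 islands in HT, 0.301% (0.225 to 0.396%) of the list, and 42 in SUDHL6, 0.319% (0.230 to 0.431%). EZH2 had 13 and 6 islands there, and H3K4me3 had 298 (2.73%) and 429 (3.12%).

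Many of the widest H3K4me3 islands of SUDHL6 lay beside long stretches without islands in any list. The widest in SUDHL6 was on chromosome 9 from 68442601 to 68491350 (48.75 kb), and the next on chromosome 21 from 10108801 to 10154700 (45.9 kb), which had no HT H3K4me3. Of the 18 SUDHL6 H3K4me3 islands of 20 kb or wider on autosomes, 13 lay within 5 Mb of the longest empty stretch of their chromosome, and 2 of 7 in HT. In these flanks H3K4me3 covered 4.31 Mb in SUDHL6 and 2.71 Mb in HT, a ratio of 1.59, and elsewhere the ratio was 1.25. The other antibodies covered less in SUDHL6 there, with a ratio of 0.607 for H3K27me3 (0.963 elsewhere) and 0.327 for EZH2 (0.843 elsewhere).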
